A study of Caenorhabditis elegans with 2 samples.

How the data were processed

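The samples were 2 biological replicates of a ChIP-seq experiment on eGFP-tagged AHA-1 in whole L4 larvae of strain OP124, numbered 1 and 2 per the labels. The labels give the antibody as aha-1 and the target as eGFP-aha-1, so whether untagged AHA-1 was also precipitated is not given in the sources used here. Their libraries had a size range of 150 to 350 bp per the labels. Per the text deposited with the samples, each replicate's peaks were called from its own alignments and a control, and a further list was called from both replicates' alignments pooled with a control, on each of the assemblies ce11 and ce10. The list of IDR peaks was thresholded by IDR with the optimal rule, as its deposited description states. The aligner, the peak caller and its settings and the IDR threshold are not given in the sources used here. The control was not analysed here.

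The deposited lists hold, per peak, its position and summit, a signal value and a −log10 q-value. The signal is the peak caller's own value of ChIP against control as deposited by the authors. How it was scaled is not given in the sources used here, so it served only to rank and describe peaks within a list. The −log10 q-values as deposited by the authors reached their maximum at 2096 peaks of replicate 1, 2621 of replicate 2 and 928 of the pooled list, so they could not rank the strongest peaks. The IDR peaks were checked to be the top of the pooled list by signal. Read counts are not in the lists, so depth is unknown. Intervals rest on numbers of peaks or genes and cover counting error only.

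The ce11 lists were set on the WBcel235 reference genome, which is the same assembly, with the gene annotation of Ensembl release 115. No coordinate was carried between assemblies, and the ce10 lists were used for numbers, widths, chromosome shares and replicate overlap. Coordinates are given from 1. A summit was placed at the position given in the list. The promoter window ran from 1000 bp upstream to 500 bp downstream of any annotated start of a protein-coding gene, and a summit in several windows counted for each gene. Non-coding genes were matched within 200 bp. Of the symbols in the lists, 11 matched no protein-coding gene of the annotation and were left out.

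The tests, the 25 gene lists, the 12 motifs and the settings to be tried besides the main ones were fixed before the data were examined. IDR peaks, or genes with an IDR summit, were compared with the remaining candidates, or genes with a candidate summit, by Fisher's exact test, two-sided. Motifs and 6-base sequences within 50 bp of the summit were compared with a window of 101 bp placed 250 bp away at higher coordinates by the exact McNemar test, two-sided. P-values were adjusted by Benjamini-Hochberg within each family, over 6 chromosomes, 25 lists, 12 motifs or 2080 sequences, and a call was an adjusted p under 0.05. Peaks and genes are the units of these tests. With 2 replicates of 1 group, no difference between conditions could be tested, and no p-value describes the spread between animals or cultures. Replicate overlap was compared with 1000 circular shifts, and loci with 1000 random windows.

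The genes named in the report follow a rule fixed with the design. It takes the genes with the nearest start at the 20 strongest IDR peaks. It takes aha-1, ahr-1, hif-1, cky-1, lin-42 and unc-119 whatever their values. From each list it takes up to 4 members with an IDR summit in the window, the highest signal first, and in lists of up to 12 members those without one. It also takes the 5 IDR peaks with the largest rank difference and the 10 sequences of 6 bases with the lowest p. Any other item is said to have been chosen after its values were seen. The gene nearest a summit need not be the gene it regulates.

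The alternatives were the ce10 lists, each replicate alone (its top 530 peaks), the stronger 265 IDR peaks, the top 1060 candidates, other overlap rules, ranking by q-value, other promoter windows, all protein-coding genes as background, the nearest start only, 10000 random draws, the lower-ranked 15000 candidates as background, other motif windows and flanks, and leaving out peaks within 25 kb of aha-1 and unc-119. Added after seeing the data were leaving out peaks near small RNA genes, keeping the 354 IDR peaks ranked 1000 or better in both replicates, keeping 1 IDR peak per 2 kb (493 peaks), matching on GC content (5 candidates per IDR peak, within 2 bases), and 100 dinucleotide-preserving shuffles.

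The list and sequence tests were checked on simulated data. Over 50 simulated sets, 1250 list tests without any effect gave 4 calls. With 3 lists planted per set, 99.3% of them were recovered, and 9 calls fell on lists that were not planted. The planted effect was strong and of a single size, so this share does not measure power for weaker effects. Simulated sequences that differed in base composition alone, by about as much as summits and flanks differ, gave 626 calls among the 2080 sequences of 6 bases, so the number of calls against the flanks does not measure motifs alone. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.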

Results

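Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the genomic sites occupied by AHA-1 in Caenorhabditis elegans L4 larvae. AHA-1 is the worm orthologue of the mammalian ARNT protein, a basic helix-loop-helix transcription factor with PAS domains that pairs with HIF-1, AHR-1 and CKY-1. The strain, OP124, carried an integrated transgene (wgIs124) with an eGFP-tagged copy of aha-1 in an unc-119 mutant background, and whole animals of both sexes were used. The labels name aha-1 as the antibody and eGFP-aha-1 as the ChIP target, so whether untagged AHA-1 was also precipitated is not known. There was 1 group with 2 biological replicates, so no condition was compared with another. Each replicate had its own list of 30000 peaks, and the list called on both replicates together also held 30000 peaks, referred to here as candidates. These lists held exactly 30000 peaks on both assemblies, so this number does not count bound sites. The candidates were deposited as peaks and background for input to IDR. Comparisons of IDR peaks with other candidates are therefore partly comparisons with background. The authors' list thresholded by the irreproducible discovery rate (IDR) held 530 peaks on the ce11 assembly. A place in it does not mean that a peak was strong in each replicate. The lists carry no read counts, so the read depth of each replicate is unknown. Confidence intervals of shares are exact Clopper-Pearson intervals and cover the counting of peaks only.

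The 530 IDR peaks were the 530 strongest candidates by the authors' signal value. Their signal ran from 25.25 to 368 with a median of 32.2, against a median of 7.08 over all candidates. The median signal was 3.91 in the list of replicate 1 and 4.87 in that of replicate 2. Median peak width was 316 bp for the IDR peaks and for the candidates. This was the largest width in both lists, held by 502 IDR peaks and 29972 candidates, so it does not measure the extent of sites.

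How well the replicates matched was measured by overlap of at least 1 bp between peaks of equal standing. Of the 100 strongest peaks of replicate 1, 54% (95% CI 43.7 to 64) overlapped one of the 100 strongest of replicate 2. At the depth of the IDR list, 235 of 530 peaks overlapped, or 44.3% (40.1 to 48.7). The share was 39.6% among the top 1000, 24.4% among the top 5000 and 27.7% among all 30000. After circular shifts of replicate 1 along each chromosome, the mean overlap was 0.344% at the top 530 and 17.9% over all peaks. The highest of the 1000 shifts gave 1.51% and 18.6%. Across matched peaks, which are not independent replicates, Spearman's rho of the ranks was 0.530 at the top 530 and 0.309 over all peaks. Requiring summits within 100 bp lowered the overlap over all peaks to 12.3%.

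Nearly all IDR peaks had a counterpart in each replicate, but many ranked far apart. Of the 530, 526 overlapped a peak in both lists. The IDR peaks came from the pooled alignments of these same replicates, so such overlap is not independent support. Over all 30000 peaks, circular shifts gave a mean overlap of 17.9%, so a counterpart of low rank can be a chance overlap. The median rank was 326.5 in replicate 1 and 297.5 in replicate 2, and 234 IDR peaks (44.2%) stood among the top 530 of both. Across IDR peaks, Spearman's rho between the ranks in the replicates was 0.168. This value cannot be compared with that across the matched peaks above. IDR peaks were the strongest by pooled signal, whereas the matched peaks had to stand high in both lists, and each selection shapes rho. A rank above 1000 was held by 96 IDR peaks in replicate 1 and by 77 in replicate 2. The 5 largest differences were at unc-119 (rank 24506 in replicate 1 and 151 in replicate 2), akt-2 (24541 and 257), col-125 (23277 and 387), pmp-2 (20052 and 169) and cel-1 (132 and 18488). The strongest peaks were close in rank: the peak upstream of egl-9 ranked 1 in both replicates, and those at mai-1 and rpl-3 ranked 3 and 4 in both.

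**Figure D1:**
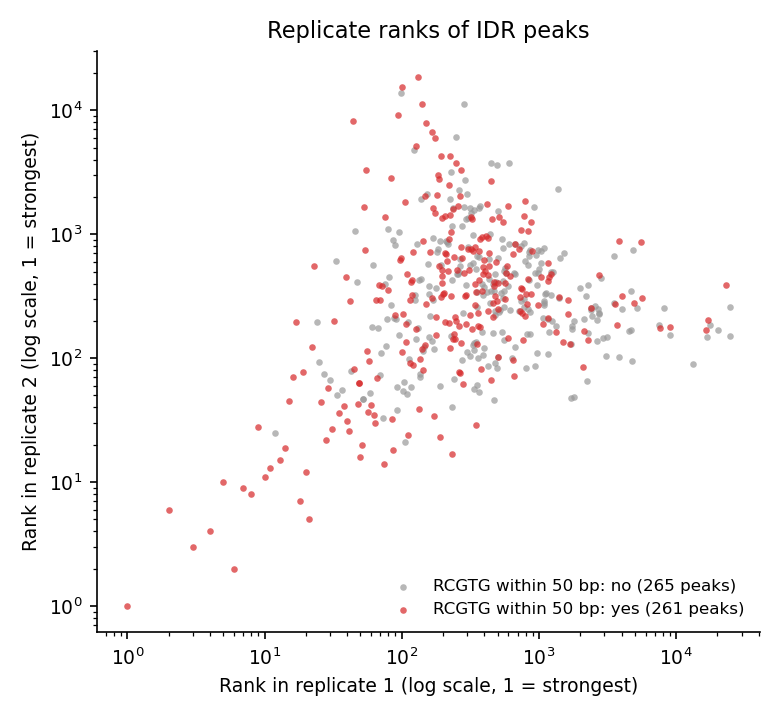
Rank of each IDR peak in replicate 1 (x axis) and replicate 2 (y axis), both on log scales with 1 the strongest, for the 526 peaks found in both lists; red points have the motif RCGTG within 50 bp of the summit and grey points lack it. The strongest peaks lie near the diagonal, and weaker ones spread to ranks above 10000 in a single replicate.

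The strongest IDR peak lay upstream of egl-9, which encodes the prolyl hydroxylase that marks HIF-1 for degradation. It spanned V:10466618-10466921 (ce11) with its summit at 10466783, outside protein-coding genes at -1734 bp from the start of egl-9 (WBGene00001178), and inside the non-coding RNA gene F22E12.9, 41 bp downstream of its start. Its signal of 368 was followed by 167 at the second peak, in an intron of ZK470.2 on X and nearest the start of ZK470.4. A further egl-9 peak, of rank 173 and signal 37.8, had its summit at -44 bp. Peaks 6 and 7 lay at nhr-57 (V:4131594-4131808, signal 148, -184 bp) and at rhy-1 (II:9160352-9160531, signal 147, -954 bp), a nuclear hormone receptor gene that responds to HIF-1 and a negative regulator of HIF-1. The IDR peak nearest hif-1 itself had rank 62, signal 57.5 and a summit at V:20778412, -1995 bp from the annotated start. This peak had no RCGTG within 50 bp of its summit.

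**Figure D2:**
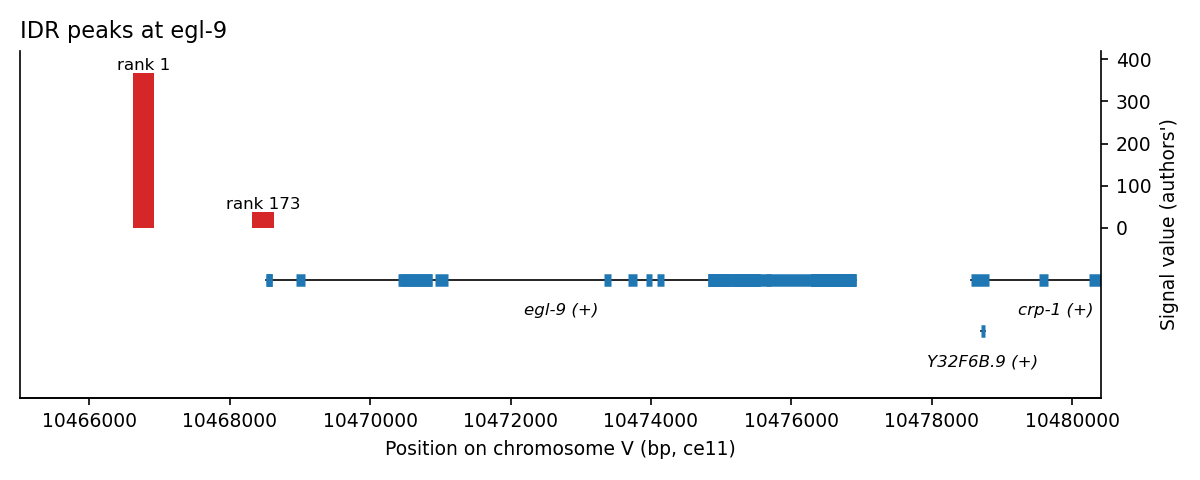
Map of V:10465017-10480415 (ce11) with the 2 IDR peaks at egl-9 as red bars whose width is the peak and whose height is the authors' signal value (right axis), above protein-coding genes (blue exons, black introns, strand in brackets). The peak of rank 1 stands upstream of the annotated start and the peak of rank 173 at it.

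The other genes nearest the 20 strongest peaks included several of central metabolism and protein synthesis. Peak 3 (X:3116305-3116518, signal 164) lay in a UTR exon of mai-1, a mitochondrial ATPase inhibitor gene just upstream of the glycolytic gene gpd-2, which is named here after its position was seen. Peak 4 (III:67142-67372, signal 163) was at -1003 bp from pck-1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase. Ribosomal protein genes stood at rank 5 (rpl-3, signal 161), 14 (rpl-15, 108) and 18 (rpl-35, 93.2). Rank 10 was an intron of hlh-30, the worm TFEB orthologue (signal 122.7), rank 11 the AAA ATPase gene cdc-48.1 (122), rank 12 the triosephosphate isomerase gene tpi-1 (118) and rank 13 the translation factor gene iff-2 (111). Methylmalonyl-CoA epimerase (mce-1) had rank 19 with signal 89.5. The remaining peaks of the 20 were nearest to H18N23.2, tasp-1, K01H12.4, F26H9.5, Y62E10A.13 and serp-1.1. For K01H12.4 (rank 15) the closest annotated start of any kind was that of the piRNA gene 21ur-8796. All of the 20 except the Y62E10A.13 peak had RCGTG within 50 bp of the summit.

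At several of these summits the core was almost central. The 31 bp around the rhy-1 summit (II:9160410-9160440) read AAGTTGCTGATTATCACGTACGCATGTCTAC on the plus strand, with the nearest RCGTG centre 1 bp from the summit. At H18N23.2 (X:17631097-17631127) the sequence was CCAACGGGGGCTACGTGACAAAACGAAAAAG, also with the core 1 bp away. At pck-1 (III:67248-67278) it was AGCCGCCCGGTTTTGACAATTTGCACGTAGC, with 3 cores within 50 bp and the nearest at 10 bp. At the strongest peak, upstream of egl-9, the only core lay 32 bp from the summit.

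Genes of protein synthesis and energy metabolism carried IDR peaks at their promoters more often than other genes. An IDR summit fell between 1000 bp upstream and 500 bp downstream of an annotated start for 418 protein-coding genes, out of 9352 with any candidate summit there. Of 73 ribosomal protein genes with a candidate, 28 had an IDR summit (38.4%, against 4.20% of other genes), among them rpl-3, rpl-15, rpl-35 and rps-12. This was an odds ratio of 14.2 (95% CI 8.42 to 23.5, Fisher's exact test two-sided, Benjamini-Hochberg (BH) adjusted p = 3.19e-18). Of 29 genes of the mitochondrial respiratory chain, 9 had one, including cox-5A, sdha-1, cox-5B and cox-6B, with an odds ratio of 9.81 (3.90 to 22.7, exact adjusted p = 3.68e-05). Of 15 glycolytic genes, 6 had one, led by ldh-1 (lactate dehydrogenase), enol-1 (enolase), gpi-1 (glucose phosphate isomerase) and ipgm-1 (phosphoglycerate mutase), with an odds ratio of 14.4 (4.21 to 45.6, exact adjusted p = 2.27e-04). The odds ratio for glycolysis was 9.0045 without replicate 1, and that for the respiratory chain was 3.68 without replicate 2 and no longer passed. The peaks near gpd-2 and tpi-1 lay outside the promoter window and were not counted.

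The HIF-1 and hypoxia list had 5 of 15 genes with an IDR summit in the window: nhr-57, rhy-1, sqrd-1 (sulfide quinone oxidoreductase), F22B5.4 and egl-9. Its odds ratio was 10.8 (2.88 to 34.9, exact adjusted p = 0.0017), 6.63 without replicate 1 and 14.8 without replicate 2, and it passed in both. Translation factors had 6 of 23, with iff-2, eef-1G, eef-1A.1 and eef-2 the strongest (odds ratio 7.64, 2.45 to 20.4, exact adjusted p = 0.0017). Chaperones had 9 of 42, led by the mitochondrial chaperonin gene hsp-60, hsp-1, hsp-90 and hsp-110 (odds ratio 5.94, 2.48 to 12.8, exact adjusted p = 4.88e-04). Their odds ratio was 3.41 without replicate 1, still passing, and 1.99, not passing, with the nearest start only. The insulin and stress list had 4 of 17, skn-1 (the Nrf orthologue), xbp-1 (a transcription factor of the unfolded protein response), atf-7 and akt-2 (odds ratio 6.63, 1.57 to 21.6, exact adjusted p = 0.021). These tests treat genes as units and do not measure variation between replicates. From the top 530 peaks of replicate 1 alone, the insulin and stress list (odds ratio 5.51) no longer passed, and from the stronger 265 IDR peaks neither chaperones (4.68) nor insulin and stress (5.43) did.

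**Figure D3:**
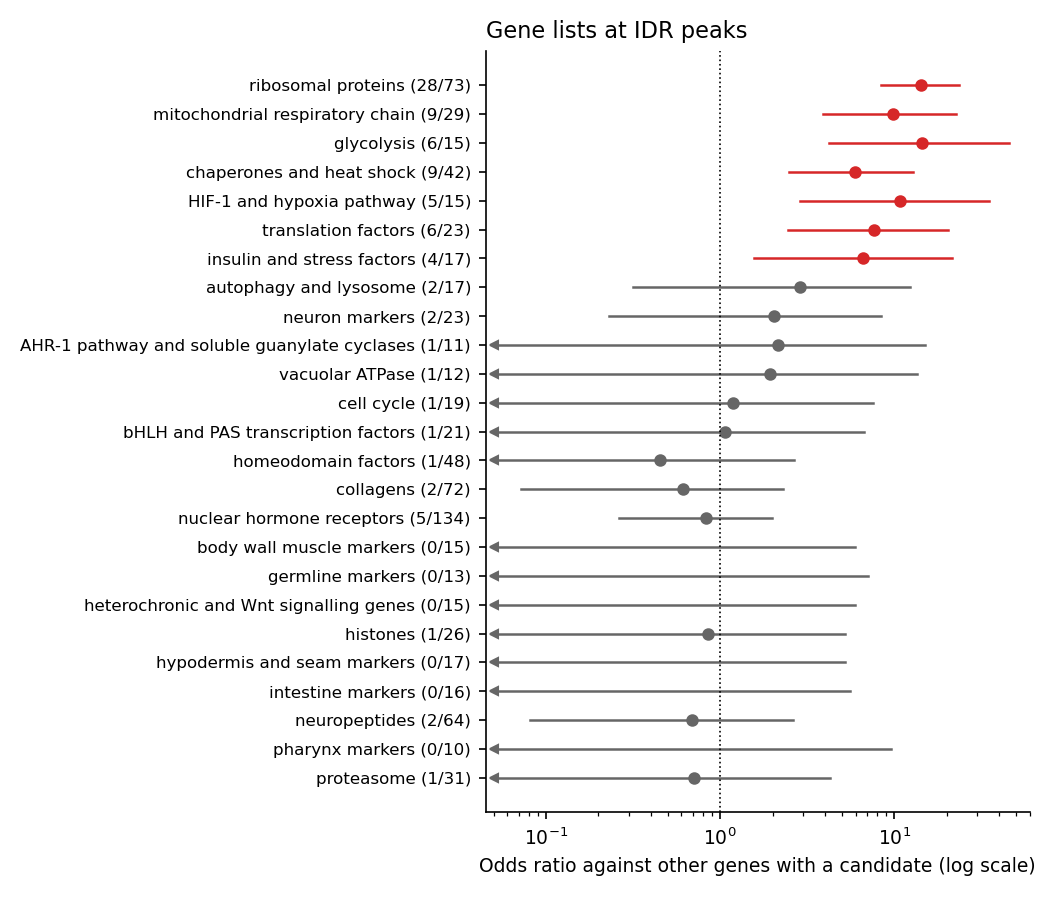
Odds ratio (x axis, log scale) for an IDR summit in the promoter window, for 25 gene lists against other genes with a candidate summit; points are odds ratios, lines 95% confidence intervals (arrowheads where they go on to the left), red lists passed the adjusted test, and brackets give genes with an IDR summit out of genes with a candidate. The 7 red lists have odds ratios from 5.94 to 14.4, and lists with 0 genes have a line and no point.

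No other list passed. Lists of tissue markers had few or no members with an IDR summit in the promoter window: 0 of 16 for intestine, 0 of 10 for pharynx, 0 of 15 for body wall muscle, 0 of 17 for hypodermis and seam, 0 of 13 for the germline, and 2 of 23 for neurons (unc-119 and egl-3). The upper 95% limits of the odds ratios with 0 members ran from 5.19 for hypodermis to 9.56 for pharynx, so an enrichment below those sizes was not excluded. The neuron count includes unc-119, which the transgene carries. Heterochronic and Wnt genes had 0 of 15. Collagens had 2 of 72 (col-38 and col-125; odds ratio 0.609, 0.0721 to 2.30), neuropeptides 2 of 64 (ins-39 and nlp-4), nuclear hormone receptors 5 of 134 (among them nhr-57, nhr-68, nhr-135 and nhr-47) and homeodomain factors 1 of 48 (ceh-38). Autophagy and lysosome genes had 2 of 17 (lgg-2 and atg-9; odds ratio 2.86, 0.316 to 12.4, Fisher's exact adjusted p = 0.546). The list of bHLH and PAS factors had 1 of 21 (mdl-1; odds ratio 1.07), the AHR-1 and guanylate cyclase list 1 of 11 (hsp-90), the vacuolar ATPase 1 of 12 (vha-12), the proteasome 1 of 31 (rpn-3), the cell cycle 1 of 19 (dpl-1) and histones 1 of 26 (his-37). The col-38 summit was nearest the start of rpl-5 and counted for both genes, and the rpn-3 summit counted for hsp-110 too. The gene rpl-5 is named here after its position was seen. Several of the list values depended on the replicate used. Without replicate 1 the odds ratio was 4.1022 for bHLH and PAS factors, 3.57 for the AHR-1 list, 3.06 for the cell cycle, 1.95 for the germline and for the proteasome, 1.53 for heterochronic and Wnt genes, 1.34 for intestine and 0.95 for homeodomain factors, none passing. Without replicate 2 it was 5.51 for bHLH and PAS factors, 5.08 for the vacuolar ATPase, 4.72 for autophagy and lysosome, 2.19 for intestine, 2.09 for histones, 1.15 for body wall muscle and 0 for collagens, homeodomain factors, the cell cycle and the proteasome, none passing. The AHR-1 list then passed with an odds ratio of 11. The vacuolar ATPase list passed with 7.85 when the 1060 strongest candidates were taken. IDR peaks near list members but outside the promoter window were not counted. Among bHLH and PAS factors these included hlh-30 (rank 10, summit at 940 bp) and hif-1 (rank 62, -1995 bp). Others, named after their values were seen, were nearest mml-1 (rank 232), the intestine marker ges-1 (525 and 526) and the heterochronic gene lin-41 (298).

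Where AHA-1 sites lie relative to genes was measured from the summits. Of the IDR summits, 314 (59.2%, 54.9 to 63.5) fell in the promoter window of a protein-coding gene, against 37.1% of the other candidates. The odds ratio was 2.46 (2.06 to 2.95, Fisher's exact test two-sided, p = 1.76e-24). Random positions on the same chromosomes fell there in 31.1% of cases on average over 1000 sets, and in 37.4% at most. Sequence between protein-coding genes held 72.5% of IDR summits and 40.1% of other candidates, and introns 20.6% and 33.1%. Coding exons held 8 IDR summits (1.51%) against 20.5% of other candidates, an odds ratio of 0.0595 (0.0255 to 0.118, exact p = 2.53e-40). UTR exons held 5.47% and 6.29%, which did not pass (odds ratio 0.862, 0.569 to 1.26, exact p = 0.526). The median distance from the summit to the nearest protein-coding start was 589 bp for IDR peaks and 1152 bp for other candidates, and 117 IDR peaks (22.1%) lay more than 2000 bp away. These classes were not adjusted for multiple testing.

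IDR peaks were also more frequent at genes for small non-coding RNAs. These genes were tested because they often carry ChIP signal of many factors in worms. No other factor was analysed here, so whether such peaks are particular to AHA-1 was not tested. Summits within 200 bp of a snoRNA gene numbered 23 (4.34%, against 0.455% of other candidates), an odds ratio of 9.93 (6.03 to 15.7, Fisher's exact test two-sided, BH-adjusted p = 3.06e-14). At snRNA genes there were 10, an odds ratio of 15.3 (6.74 to 31.6, exact adjusted p = 1.57e-08). Of these 10, the strongest were at sls-2.2 (rank 36), sup-6 (83) and sls-2.1 (87), named here after their values were seen. Another of the 10, of rank 279, overlapped the peak of rank 36, so sls-2.2 was counted more than once. At tRNA genes there were 22, an odds ratio of 4.01 (2.45 to 6.24, exact adjusted p = 2.47e-07), and 13 of them lay on X, where 276 of the 612 annotated tRNA genes lie. Among the stronger 265 IDR peaks the tRNA odds ratio was 1.42 and no longer passed. The 3 peaks near miRNA genes (cel-mir-5549, cel-mir-5595 and cel-mir-52, also named afterwards) did not pass (odds ratio 3.22, 0.641 to 10, exact adjusted p = 0.0733), although the class passed without replicate 1 (3.86), without replicate 2 (4.30) and with 1060 candidates (4.67). No candidate summit lay within 200 bp of an rRNA gene.

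Chromosome X held more IDR peaks than its share of candidates. It carried 138 of the 530 (26.0%, 22.3 to 30), against 19.2% of the other candidates, an odds ratio of 1.48 (1.21 to 1.80, Fisher's exact test two-sided, BH-adjusted p = 9.32e-04). This was 7.79 IDR peaks per Mb on X, against 3.44 on V and 3.54 on IV. Chromosome V (odds ratio 0.701, 0.538 to 0.902, exact adjusted p = 0.009) and chromosome IV (0.654, 0.493 to 0.856, exact adjusted p = 0.0037) held fewer. Chromosomes I, II and III did not pass. The odds ratio for X ran from 1.31 to 1.69 over all settings and passed in each, whereas that for IV did not pass from either replicate alone (0.783 without replicate 1 and 0.780 without replicate 2).

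The sequence at IDR summits was rich in the RCGTG core, which covers the sites of HIF and other ARNT dimers. RCGTG occurred within 50 bp of the summit in 262 peaks (49.4%, 45.1 to 53.8), against 15.5% in windows 250 bp away from the same peaks (exact McNemar test two-sided, BH-adjusted p = 3.25e-30). Other candidates had it in 15.8% (odds ratio 5.2, 4.36 to 6.21, Fisher's exact adjusted p = 1.33e-69). Its forms ACGTG and GCGTG each stood at 8.30% in the flanks and at 28.9% and 27.9% at the summits (exact adjusted p = 5.25e-19 and 1.84e-15). The palindrome CACGTG, the site of ARNT homodimers, occurred in 7.92% of summits and 0.943% of flanks (exact adjusted p = 1.88e-09), and in 4.53% of summits, still passing, without replicate 1. TNGCGTG, the dioxin response type of site, occurred in 6.42% and 2.26% (exact adjusted p = 0.0019). GAGAGA was found in 26.2% of summits and 9.06% of flanks (exact adjusted p = 1.73e-13). The GATA motif WGATAR was less frequent at summits (13.2% against 23.8%, exact adjusted p = 1.73e-05), as was the forkhead motif TRTTKRY (22.5% against 29.8%, exact adjusted p = 0.0112), which did not pass without replicate 2 (27% of summits) or within 100 bp of the summit. TNGCGTG did not pass within 25 bp (3.4% of summits). The direction for TRTTKRY depended on the comparison, and against shuffled summit sequences (17% on average) it passed as more frequent (permutation adjusted p = 0.0339, the smallest that the 100 shuffles allow here).

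CANNTG sites other than CACGTG occurred in 39.4% of summits and 28.5% of flanks (exact adjusted p = 5.35e-04), and TCGTGA in 4.34% and 1.89% (exact adjusted p = 0.0421). TCGTGA did not pass without replicate 1 (4.34% of summits) or without replicate 2 (3.96%), and neither motif passed within 25 or 100 bp of the summit. TGACGTCA (0.755% and 0.377%, exact adjusted p = 0.688) and CCGGAA (0.943% and 2.45%, exact adjusted p = 0.105) did not pass against the flanks, and CCGGAA was rarer than at other candidates (odds ratio 0.236, 0.0761 to 0.555, Fisher's exact adjusted p = 1.23e-04). Without replicate 2, TGACGTCA stood at 1.32% of summits and CCGGAA at 1.51% (odds ratio 0.362 against other candidates). IDR summits were also richer in G and C, at 49.4% against 35.4% in their flanks and 36.6% at other candidates. Against 2650 other candidates of like GC content, a comparison chosen after seeing the data, RCGTG stood at 28.9% (odds ratio 2.41) and passed, as did ACGTG (2.57), CACGTG (2.54), GAGAGA (2.14), GCGTG (1.83), TNGCGTG (1.68) and, as less frequent, CCGGAA (0.196), whereas WGATAR (0.984), TRTTKRY (1.21), CANNTG (1.23), TCGTGA (1.29) and TGACGTCA (1.05) did not. Against summit sequences shuffled with their dinucleotides kept, also chosen afterwards, RCGTG averaged 39.2%, ACGTG 19.4%, CACGTG 3.65%, GAGAGA 11.9% and CANNTG 33.1%, and these and TRTTKRY passed as more frequent at summits. CCGGAA (3.48%) passed as less frequent, and GCGTG (25.4%), TNGCGTG (6.79%), WGATAR (11.9%), TCGTGA and TGACGTCA did not pass.

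**Figure D4:**
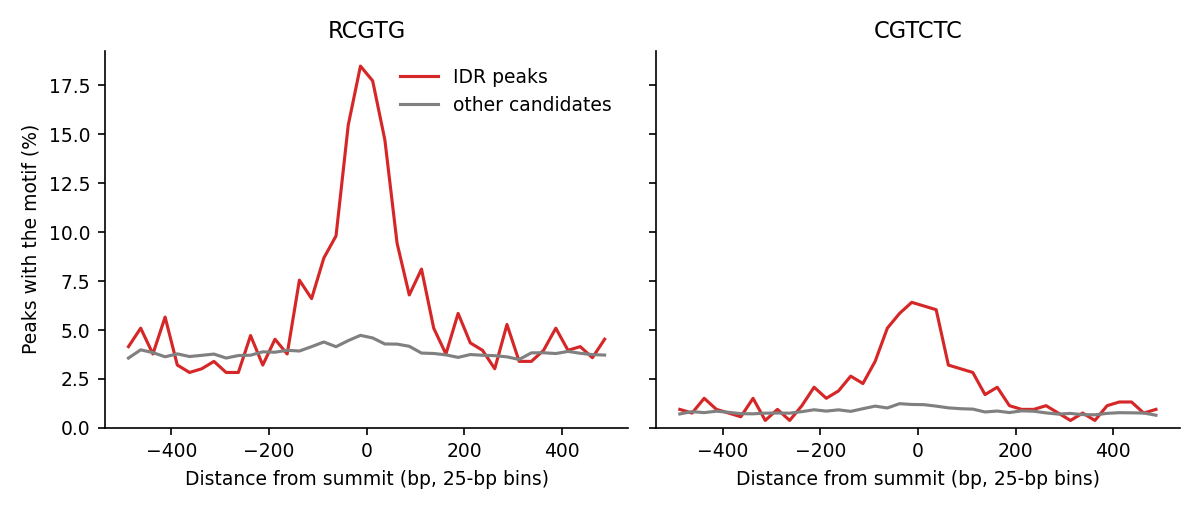
Percent of peaks (y axis) with RCGTG (left) or CGTCTC (right) in 25-bp bins up to 500 bp on each side of the summit (x axis, bp), for IDR peaks (red) and other candidates (grey). In the bin just below the summit RCGTG stands at 18.5% of IDR peaks and 4.73% of other candidates, and CGTCTC at 6.42% and 1.19%.

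The share of peaks with RCGTG was highest at the strongest peaks. It was 80% (66.3 to 90) in the first 50 peaks, 48% in the next 50, 52% in the 100 after those and 44.2% (38.8 to 49.8) in the remaining 330 IDR peaks. Below the IDR threshold it was 34.9% at ranks 531 to 1000 and 14.3% (13.8 to 14.8) at ranks 10001 to 30000. GAGAGA stayed between 22% and 27.9% in the intervals up to rank 1000 and was 6.42% at ranks 10001 to 30000. No trend test was run.

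**Figure D5:**
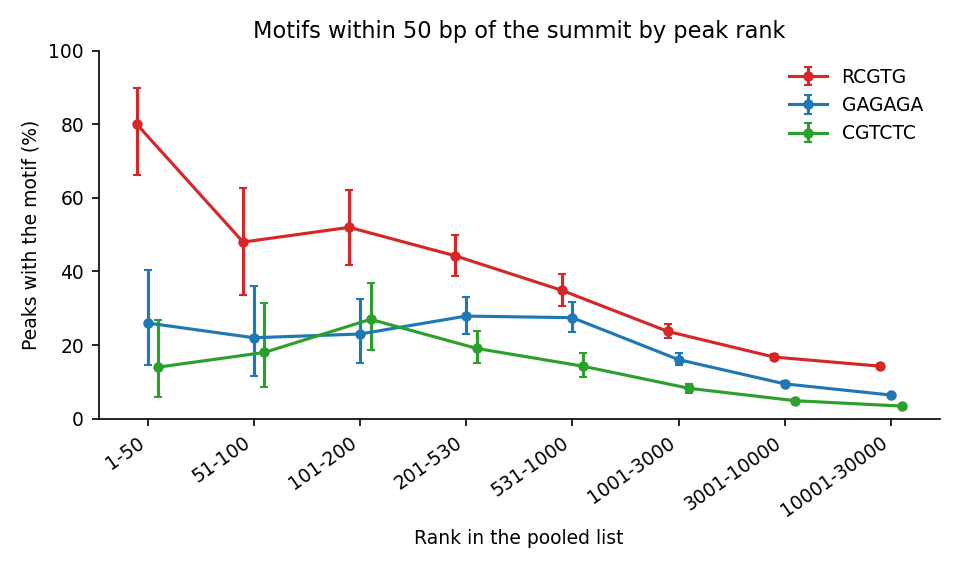
Percent of peaks (y axis) with RCGTG, GAGAGA or CGTCTC within 50 bp of the summit, by interval of rank in the list called on both replicates together (x axis); error bars are exact 95% confidence intervals over peaks. RCGTG falls from 80% at ranks 1 to 50 to 14.3% at ranks 10001 to 30000.

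Among all sequences of 6 bases, with strands merged, 355 were more frequent and 260 less frequent at IDR summits than in the flanks (exact McNemar test two-sided, BH-adjusted). Without replicate 1 these numbers were 242 and 170, with the stronger 265 peaks 183 and 132, and within 25 bp of the summit 210 and 169. The 10 with the lowest p included AGAGAC (21.7% of summits and 3.4% of flanks, exact adjusted p = 3.62e-18) and CGTCTC (20% and 3.58%, exact adjusted p = 8.42e-15). The other 8 of the 10 held only A and T and were rarer at summits: TAAAAA, AAAAAT, AAAATT, TTAAAA, AAAAAA, TTTAAA, AAAATA and AATAAT. In simulated sequences, a difference in base composition of this size gave 626 calls with no motif present. Against other candidates of like GC content, 262 passed, 136 as more and 126 as less frequent. Of the 10 named, only AGAGAC (odds ratio 2.65) and CGTCTC (2.03) then did.

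Among aha-1 and the genes of possible partners of AHA-1, only hif-1 had an IDR peak nearby. The strongest candidate near aha-1 (WBGene00000095, I:10193925-10196997) had rank 735 and a signal of 21.8. It overlapped a peak of rank 163 in replicate 1 and 3334 in replicate 2. The strongest near ahr-1, cky-1 and lin-42 had ranks 6440, 6426 and 708, so none was an IDR peak, but that at lin-42 had rank 279 in replicate 1 and no match in replicate 2. Within 25 kb of aha-1 there were 8 candidates and 0 IDR peaks, and 95.4% of 1000 random windows on the same chromosome held as many candidates. Within 10 kb there were 2 candidates (97.1% of windows held as many) and within 50 kb 30 (59.4%). The unc-119 gene (WBGene00006843, III:10902641-10908935) held 3 IDR peaks with signals of 44.0, 40.1 and 26.7. Within 25 kb of it there were 23 candidates, and 19.9% of random windows held as many, whereas 0.6% held as many IDR peaks. Within 10 kb there were 16 candidates against a median of 8 (5.7% of windows held as many, and 0.5% as many IDR peaks). Within 50 kb there were 36 against 34 (42.2% and 5%).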

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

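Of 796 values under other settings, 680 kept their direction and side of the threshold or stayed within their interval, 36 fell below the threshold, 10 rose above it, 53 crossed to the other direction and 17 moved; the GC-matched, shuffled, small RNA, 2 kb and consistent-rank settings were chosen after seeing the data. The lists of ribosomal proteins, glycolysis, HIF-1 and hypoxia, and translation factors, the promoter share, chromosome X and RCGTG passed in every setting run on them. No paired analysis was possible because there was 1 group. Ranking by q-value was not run for the top 100, 530 and 1000, where the maximum is tied. Where a call was lost or gained, the cause was not tested. Depth is unknown and its effect could not be measured.

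The odds ratio for chaperones no longer passed with the nearest start only (1.99), with the 354 IDR peaks of consistent rank (3.67) and with the stronger 265 (4.68). That for insulin and stress no longer passed with 1060 candidates (3.37), consistent rank (4.38), the 500 bp window (3.1) and the stronger 265 peaks (5.43), and ran from 5.51 (not passing, without replicate 2) to 8.31 with a replicate left out. Over the same 2 settings the respiratory chain ran from 3.68 (not passing, without replicate 2) to 7.91, and the AHR-1 list from 3.57 to 11 (passing, without replicate 2); with the nearest start only the AHR-1 list gave 0. The vacuolar ATPase passed with 1060 candidates (7.85). Chromosome IV did not pass without either replicate (0.780 and 0.783), at consistent rank (0.701) or in the stronger 265 peaks (0.852).

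Among 6-base sequences, 262 passed against GC-matched candidates, 315 with the stronger 265 peaks and 379 within 25 bp. Replicate overlap fell with a reciprocal overlap of 50% to 35.3% at 1000, 19.6% at 5000 and 16.6% at 30000 peaks, and with summits within 100 bp to 39.1% at 530, 32.2%, 16.5% and 12.3%.

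The values that crossed 1, or the flank share, belong to results that did not pass, apart from WGATAR and TNGCGTG against other candidates. With 1060 candidates the odds ratio was 1.68 for body wall muscle and for heterochronic and Wnt genes, 1.99 for histones, 2.53 for intestine and 1.62 for the proteasome. With the 2000 bp window it was 0.871 for the cell cycle, 1.05 for the germline, 1.16 for heterochronic genes and histones, 1.31 for intestine and 1.24 for nuclear hormone receptors. With the 500 bp window it was 0 for the cell cycle and neurons, 1.26 for collagens and 1.18 for histones. With random draws the ratio of observed to drawn was 1.32 for collagens, 1.89 for histones, 1.33 for neuropeptides, 1.43 for nuclear hormone receptors and 1.34 for the proteasome. The draws took candidates wherever they lay, and 59.2% of IDR summits but 37.1% of other candidates fell in a promoter window. A drawn ratio above 1 can thus arise without enrichment of a list. With the nearest start the odds ratio was 1.84 for histones and 1.07 for the proteasome, and with all protein-coding genes 1.46 for the proteasome. With the stronger 265 peaks it was 1.62 for histones, 1.35 for the proteasome and 0.948 for chromosome I; at consistent rank it was 1.31 for histones, 1.01 for nuclear hormone receptors and 0.904 for chromosome I. Chromosome II gave 0.987 without peaks near small RNA genes.

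With a replicate left out, the odds ratio ran from 0 to 1.15 for body wall muscle, 0 to 3.06 for the cell cycle, 0 to 1.95 for the germline, 0 to 1.53 for heterochronic genes, 0.929 to 2.09 for histones, 1.34 to 2.19 for intestine, 0 to 1.95 for the proteasome, 0.927 to 1.07 for chromosome I and 0.946 to 1.07 for chromosome II. TRTTKRY against other candidates ran from 0.936 to 1.1, and TGACGTCA from 0.566% to 1.32% of summits.

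TGACGTCA stood at 0.282% of summits at consistent rank (odds ratio 0.522 against other candidates), and at 0.377% in the stronger 265 peaks (0.698) and within 25 bp. Against shuffled summits the ratio was 0.698 for TCGTGA, 0.941 for TNGCGTG, 1.41 for TRTTKRY and 1.13 for WGATAR; TRTTKRY, lower in the flank comparison, passed as higher against the shuffles and stood at 1.21 against GC-matched candidates, without passing.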

Other observations

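The gene lists in the next paragraphs, and the tests of the unc-119 cluster, of abundant mRNAs, of CGTCTC at ribosomal promoters, of separate sets of peaks and of unmatched peaks in replicate 2, were chosen only after the results were seen. The gene lists were written after reading the names of genes at IDR peaks on the same data, so their p-values are not independent evidence. Genes named in these paragraphs were chosen after their values were seen.

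All 4 genes of canonical propionate breakdown had an IDR summit in the promoter window: mce-1 (rank 19), pccb-1 (23), pcca-1 (46) and mmcm-1 (71), which encode methylmalonyl-CoA epimerase, the subunits of propionyl-CoA carboxylase and methylmalonyl-CoA mutase. The lower 95% limit of the odds ratio was 14.2 (Fisher's exact test two-sided, adjusted p = 9.84e-06 over 5 lists). For the fixed lists, at least 5 genes with a candidate were required for a test, and this minimum was not applied here. Of 4 genes with a candidate in the alternative propionate pathway, 0 had an IDR summit (upper limit 32.4), so a difference between the pathways was not tested. The TCA cycle had 7 of 21 genes (sdha-1, mdh-1, mev-1, sucl-1, dld-1, sdhd-1 and aco-2; odds ratio 10.9, 3.68 to 28.9, exact adjusted p = 3.81e-05), of which sdha-1 and sdhd-1 are also in the respiratory chain list.

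Genes of protein entry into and folding in the endoplasmic reticulum had 10 of 20 members with an IDR summit (odds ratio 21.9, 8.11 to 58.8, exact adjusted p = 1.77e-08). They were the transcription factor genes xbp-1 and atf-6, the chaperone genes crt-1 and hsp-3, the disulfide isomerase genes pdi-2 and pdi-6, and sec-61.B, sec-61.G, trap-2 and trap-3. A single summit between sec-61.B and trap-3 counted for both. Jumonji domain genes had 3 of 7 (jmjd-1.2, rbr-2 and jmjd-4), with the jmjd-4 summit shared with mev-1. Their odds ratio was 16.1 (2.35 to 95.6, Fisher's exact test, adjusted p = 0.0034). Against other candidates of like GC content, the 6-base sequence with the lowest p was CACGTA, read as TACGTG on the other strand. It occurred at 13.2% of IDR summits and 2% of matched candidates (odds ratio 7.46, Fisher's exact adjusted p = 6.71e-22, all sequences of 6 bases tested).

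The unc-119 gene held 3 IDR peaks, including a coding exon peak, and the strain carries unc-119 on its transgene. Extra copies of the whole transgene, extra copies of the unc-119 segment alone and occupancy by AHA-1 at the gene itself cannot be told apart without read coverage. Within 25 kb of aha-1 there were 8 candidate summits against a median of 16 in random windows, but around unc-119 itself 19.9% of random windows held as many, so this count does not measure copies. With the 3 IDR peaks left out, candidate summits were 1.99 times as dense inside the gene as in the 25 kb on both sides (4 inside and 16 outside, 95% CI 0.483 to 6.16, exact binomial test two-sided, p = 0.272), too few to decide.

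The excess of IDR peaks on X was set against 3 explanations. Stratified by location, the odds ratio for X was 1.52 (1.25 to 1.86), and stratified by RCGTG it was 1.39 (1.14 to 1.70), so neither a difference in location nor in RCGTG is likely to be the whole cause. A signal raised along all of X was not excluded. Among candidates in coding exons the odds ratio for X in the top 3000 was 0.806 (0.545 to 1.16, Fisher's exact p = 0.265). This interval reaches above 1.1, the limit set beforehand. It lies below the odds ratio of 1.48 for X among IDR peaks, but that value rests on a different cut of the list. With 1 group, no biological difference between groups was tested.

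Peaks at ribosomal protein gene promoters might reflect recovery of promoters of abundant mRNAs in general. Collagen and body wall muscle genes, which are abundantly expressed in larvae, had 2 of 87 genes with an IDR summit, an odds ratio of 0.5005 (0.0594 to 1.88). The col-38 summit counted among them was shared with the ribosomal protein gene rpl-5. The proteasome (0.712, 0.0174 to 4.30) and histones (0.855, 0.0208 to 5.25) did not pass either, with wide intervals. Translation factors (7.64), the respiratory chain (9.81), glycolysis (14.4) and chaperones (5.94) were enriched. Recovery of promoters of abundant mRNAs therefore cannot be told apart from binding at these genes. RCGTG occurred at 13 of 27 ribosomal summits and 148 of 287 other IDR promoter summits (odds ratio 0.872, 0.363 to 2.08, Fisher's exact p = 0.841), which leaves sites with the core open. CGTCTC occurred at 2 of 27 (7.41%, 0.910 to 24.3), which argues against a CGTCTC element shared by most of them. No difference between groups was tested, since there was 1 group.

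A hypothesis that RCGTG and CGTCTC mark separate sets of peaks was tested. RCGTG occurred in 50% (40.1 to 59.9) of IDR peaks with CGTCTC, above the 28.9% of GC-matched candidates, which were not IDR peaks. It occurred in 49.3% of IDR peaks without CGTCTC (odds ratio 1.03, 0.657 to 1.61, Fisher's exact test two-sided, p = 0.914). These shares argue against wholly separate sets, but the interval leaves a partial separation open. A hypothesis that strong peaks without a match in the other replicate carry RCGTG less often was tested on the top 530 of each replicate. In replicate 1 the core occurred in 52.8% of 235 matched and 47.5% of 295 unmatched peaks (odds ratio 1.24, 0.865 to 1.77, exact p = 0.256), which does not settle it. In replicate 2 the shares were 54% and 33.8% (odds ratio 2.30, 1.59 to 3.32, Fisher's exact test two-sided, p = 4.09e-06), and the difference between the replicates was not tested. Rank was not held equal between matched and unmatched peaks. Since RCGTG was most frequent at the strongest peaks, a difference in strength between them cannot be told apart from one in matching.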
